A study of Mus musculus with 26 samples.

How the data were processed

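The series measured RNA from 26 mouse samples on the Affymetrix Mouse Exon 1.0 ST array, which carries several probe sets for each gene, mostly 1 or more per exon. Per the labels' protocols, RNA was isolated with a column kit made to keep small RNAs together with an RNase inhibitor, freed of genomic DNA, amplified in 2 rounds and converted to labelled single-stranded cDNA. Per the labels, the deposited values are RMA expression values from an extended-exon analysis in Affymetrix Expression Console, whose version is not given in the sources used here. RMA corrects the background, normalizes the arrays to a common distribution and summarises the probes of each probe set, so the values deposited by the authors are log2 values per probe set. The log base was taken as 2 from RMA convention and from the value range, 0.831 to 15.6. The table held 631748 probe sets with 0 missing values, and all of its columns mapped to a sample. The per-array median lay between 5.32 and 5.51. Arrays give no read depth, and the number of arrays limits the precision.

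Samples were grouped by the strain in their labels, 14 arrays labelled 129S2/SvPas and 12 labelled C57BL/6. The labels abbreviate the whole set as ES and EB, read here as embryonic stem cells and embryoid bodies, but call each sample an embryoid body cell, so no sample was assigned to either kind. The titles ES1 to ES26 are used as names: ES1 to ES14 carry the first strain label and ES15 to ES26 the second. No label gives a scan date or a batch, and the strain label follows the order of the titles, so an unrecorded batch and the strain cannot be told apart. Nothing states that the samples came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. No pair of arrays held identical values.

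Gene names came from the platform annotation, which gave 1 symbol for 306069 probe sets (48.4%), several for 6067 and none for 319612. Of its 21757 symbols, 17747 were current in the RefSeq gene table of assembly GRCm38.p6, 3725 were updated through a unique synonym and 285 were kept as given. The genome build behind the annotation is not given in the sources used here, so no coordinates are printed. A gene value was the median over the brighter part, rounded up from 50%, of the gene's probe sets ranked by their mean over all arrays. The 18341 genes with at least 4 probe sets were tested, with a median of 13 probe sets.

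Differences are 129S2/SvPas minus C57BL/6 as labelled. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided moderated test, Benjamini-Hochberg adjustment, threshold 0.05) on gene values and on all probe set values. For probe sets within genes, the gene value of the same array was subtracted, and the 156023 probe sets above the median gene and the median probe set were tested without a trend and with a minimum difference of 1 log2 unit. Of 24 gene lists holding 642 distinct genes, 574 genes were tested, with camera at a preset inter-gene correlation of 0.01. The spread within each label was tested with limma on absolute deviations from the label's median. Named genes were chosen by a rule: the 12 largest differences in each direction among genes past the threshold with at least 0.75 of their probe sets shifted alike and no provisional name, up to 4 genes per list with the largest difference past the threshold (the smallest p where none passed), all tested members of the list of reported strain variants, the 6 genes with the largest ratio of spread in each direction, and the 6 largest differences of probe sets within genes at 1 per gene. The tests, lists, naming rule and alternatives were fixed before the data were examined. The alternatives covered the gene summary, the minimum of probe sets, filters on dim genes, normalization, the eBayes and array weight settings, a covariate, the thresholds and each array left out in turn. Settings that leave out ES13 and ES14, or ES1 to ES12, were added after the data were seen, as were 6 blood cell lists (stem and progenitor, B cell, T cell, myeloid, definitive erythroid, megakaryocyte) used in the closing part. Correlations between list scores were planned within each strain but not computed, because the scores fell into separate clusters.

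The steps were tested on simulated data. Values were drawn independently from a normal distribution for each gene and array, at the gene's SD pooled over the labels. Real arrays resembled their neighbours and genes of several lists were correlated, so the rates below may not hold for them. For the gene comparison, 40% of 50 genes changed by 0.5 log2 units were recovered among 18341 genes, 86% at 1, 96% at 2 and 100% at 4, with 8 false calls. For the spread comparison, 30.5% of 200 genes with a 4-fold larger SD were recovered with 0 false calls. The probe set comparison recovered 92.5% of 200 probe sets changed by 2 log2 units among 631748, with 12 false calls, and the comparison within genes 100% of 200 among 156023, with 1. Splits of the samples were drawn with a fixed seed. A further test, added after the data were seen, moved the run of 14 labels round the order of the titles. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for preparation, the closing tests and the plots.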

Results

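The data are RMA log2 values from 26 exon arrays of mouse samples described as embryonic stem (ES) cells and embryoid bodies, the aggregates in which ES cells differentiate. The only grouping in the labels is the mouse strain, with 14 arrays labelled 129S2/SvPas and 12 labelled C57BL/6, 2 inbred strains commonly used to derive ES cells. The comparison the design allows is therefore between strain labels, at the level of genes, probe sets, probe sets within genes, gene lists and spread.

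The arrays did not group by their strain labels. ES13 and ES14, labelled 129S2/SvPas, had a mean gene correlation of 0.833 and 0.836 with the other arrays of that label, and of 0.944 and 0.948 with the arrays labelled C57BL/6. The neutrophil granule gene Ngp lay between 11.02 and 13.50 in ES1 to ES12, at 5.13 in ES13 and 4.69 in ES14, and between 3.64 and 5.34 in the arrays labelled C57BL/6. Xist, the RNA that coats the inactive X chromosome, lay between 12.00 and 12.43 in ES1 to ES12 and was 4.84 in ES13 and 4.48 in ES14. The Y-linked translation factor gene Eif2s3y lay between 2.77 and 4.03 in ES1 to ES12, and was 9.60 and 9.63 in ES13 and ES14. Because these values go against a single group of 14, groups are called "labelled 129S2/SvPas" and "labelled C57BL/6" throughout, and values for ES13 and ES14 are given beside the gene lists that passed and beside several of the named genes.

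**Figure D1:**
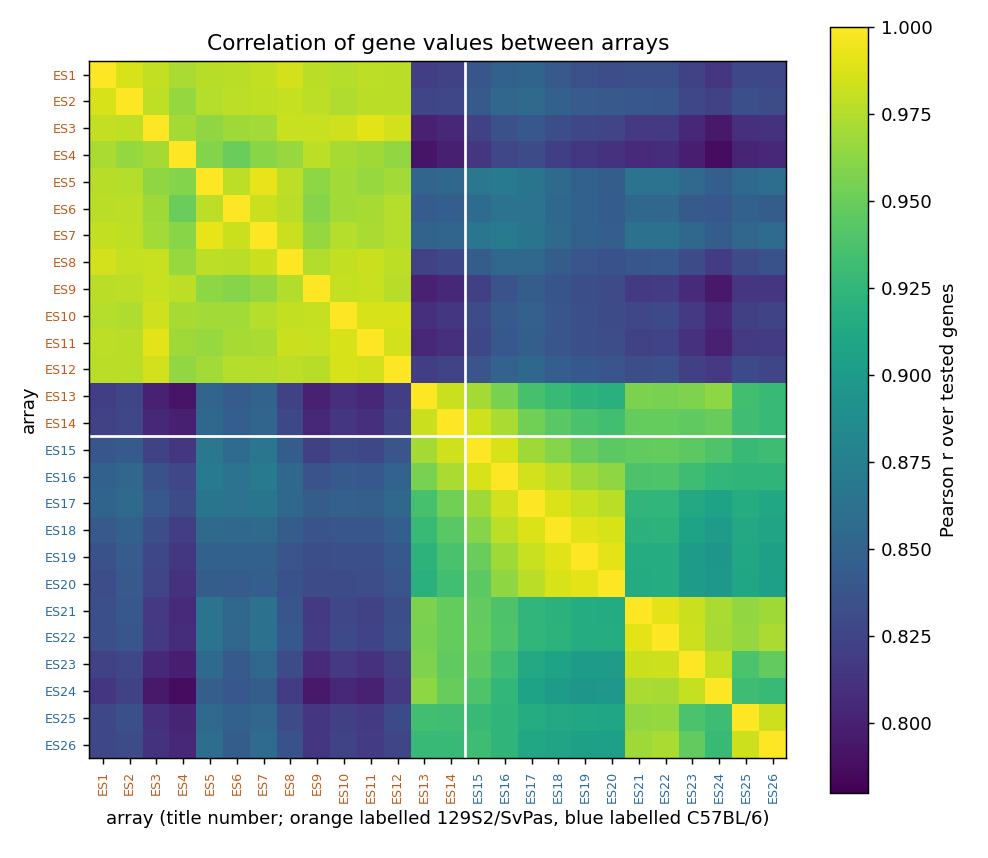
Heat map of Pearson correlations over the 18341 tested genes between all pairs of the 26 arrays, in title order on both axes, with white lines between the strain labels. ES13 and ES14 lie above the lines but share their higher correlations with the arrays labelled C57BL/6, at means of 0.944 and 0.948.

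At the gene level, the named genes most strongly higher in the arrays labelled 129S2/SvPas were led by Chil3. Chil3, a chitinase-like protein of macrophages and neutrophil precursors, averaged 11.21 ± 3.55 (SD, n = 14) against 3.02 ± 0.39 (SD, n = 12), a difference of 8.19 ± 0.97 log2 units (SE; limma adjusted p = 3.59e-07). Its paralog Chil4, the granulocyte and monocyte progenitor gene Ms4a3, the neutrophil collagenase Mmp8, Ngp, the mast cell carboxypeptidase Cpa3, the myeloid lectin Clec5a, Xist, the neutrophil lipocalin Lcn2, the mast cell membrane gene Mcemp1, the glucocorticoid-activating enzyme Hsd11b1 and Ela2, an elastase symbol kept as annotated, followed with differences from 7.90 to 5.84. Chil3 and Chil4 are near-identical paralogs, so signal shared between their probe sets is possible. With the mean over all probe sets as gene value, the differences of Chil4 and Hsd11b1 were 4.69 and 3.85. Over these 12 genes, ES1 to ES12 ranged from 9.41 to 13.50, ES13 and ES14 from 2.57 to 5.86, and the arrays labelled C57BL/6 from 2.21 to 6.37.

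The named genes most strongly lower in the arrays labelled 129S2/SvPas were led by Slc38a4. Slc38a4, an imprinted amino acid transporter gene, averaged 6.46 ± 2.64 (SD, n = 14) against 12.31 ± 0.33 (SD, n = 12) and differed by -5.85 ± 0.73 log2 units (SE; limma adjusted p = 5.94e-07). The others were the imprinted noncoding RNA Rian (-5.66), the kinase gene Rps6ka6 (-5.27), Eif2s3y (-5.07), the basement membrane gene Nid1 (-5.01), the connexin gene Gjc1 (-4.94), the pluripotency gene Dppa5a (-4.91), imprinted Peg3 (-4.83), the RNA-binding protein gene Igf2bp1 (-4.79), the growth hormone receptor Ghr (-4.78), the hyaluronan synthase Has2 (-4.78) and the protocadherin gene Fat1 (-4.75). With the mean over all probe sets, Gjc1 differed by -3.24. Over these 12 genes, ES1 to ES12 ranged from 2.77 to 6.11, ES13 and ES14 from 8.05 to 12.79, and the arrays labelled C57BL/6 from 7.34 to 12.70.

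Of 18341 genes, 7931 passed the threshold, 3876 higher and 4055 lower in the arrays labelled 129S2/SvPas, and 1384 of the higher and 1576 of the lower genes differed at least 2-fold. Centring each array on its median moved the median difference of all genes from 0.00 to 0.13, and the share of calls that were higher from 48.9% to 66%, so small differences have to be read against that shift. Without ES1 to ES12, which leaves ES13 and ES14 against 12 arrays, 1 gene passed the threshold by limma and 1814 had an unadjusted p below 0.05. That gene, named after its value was seen, was the primitive streak gene Mixl1, higher by 3.93 in ES13 and ES14 (adjusted p = 0.00485).

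**Figure D2:**
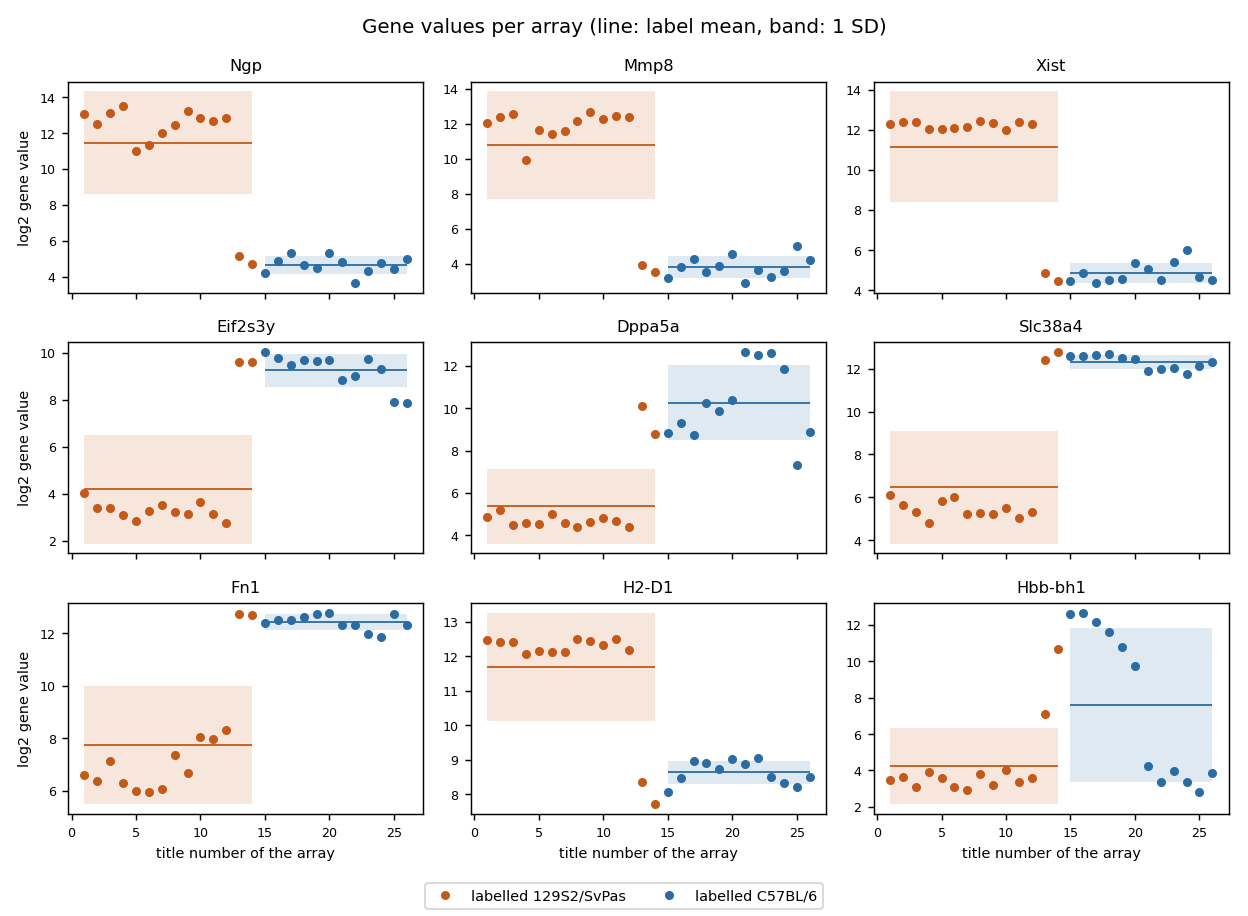
Log2 gene values of 9 named genes on the vertical axes against the title number of the array, with orange points for the label 129S2/SvPas, blue points for C57BL/6, a line at each label's mean and a band of 1 SD. ES13 and ES14 lie with the blue points for Ngp, Mmp8, Xist, Eif2s3y, Slc38a4 and Fn1, and Hbb-bh1 spans 2.82 to 12.67 within the label C57BL/6.

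Pluripotency genes were lower in the arrays labelled 129S2/SvPas. Of 32 tested members of the naive pluripotency list, 24 were lower and 0 higher, and the same numbers passed when adjusted over the list alone. Beside Dppa5a, the largest differences were those of the Nodal co-receptor Tdgf1 (-4.11 ± 0.80, SE), the zinc finger gene Zfp42 (-3.98 ± 0.64) and the chromatin gene Utf1 (-3.96 ± 0.67). The list passed the threshold with camera (median -1.98, adjusted p = 1.1e-07), and not with an estimated correlation (adjusted p = 0.415). The list score, the mean of its members, lay between 6.35 and 6.57 in ES1 to ES12, was 8.33 in ES13 and 7.77 in ES14, and lay between 7.20 and 10.77 in the arrays labelled C57BL/6. Of 17 primed epiblast genes, 6 were lower (4 adjusted over the list alone), led by the tight junction gene Cldn6 (-3.26), the de novo DNA methyltransferase Dnmt3b (-1.32), Fgf5 (-1.09) and the homeobox gene Otx2 (-0.96), with a list adjusted p = 0.00649, an adjusted p = 0.574 with an estimated correlation and an adjusted p = 0.192 without the dimmer 50% of genes. Dnmt3b did not pass with arrays centred on their median (adjusted p = 0.0585) and had a difference of medians of -2.07, and Cldn6 and Otx2 differed by -1.74 and -1.64 with the mean over all probe sets. The primed epiblast score was 6.12 to 6.84 in ES1 to ES12, 8.36 in ES13, 7.65 in ES14 and 6.62 to 8.40 in the arrays labelled C57BL/6. Of 16 germ cell and 2-cell-like genes 9 were lower, among them Tfap2c (-1.98), the meiotic genes Sycp3 (-1.06) and Hormad1 (-0.89) and the RNA helicase Ddx4 (-0.90). That list had an adjusted p = 0.0217, and an adjusted p = 0.692 with an estimated correlation, and its score was 4.43 to 4.75 in ES1 to ES12, 5.46 in ES13, 5.10 in ES14 and 4.47 to 6.59 in the arrays labelled C57BL/6. Sycp3 did not pass with the median over all probe sets (-0.60, adjusted p = 0.123) or their mean (-0.49, adjusted p = 0.065), nor Ddx4 with arrays centred on their median (adjusted p = 0.0592) or Hormad1 by the rank sum test (adjusted p = 0.061). With the mean over all probe sets, Tfap2c differed by -1.24 and Hormad1 by -0.43.

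The extraembryonic endoderm, trophoblast, cardiac, neural and Hox lists passed as lower with the preset correlation, with 7 to 18 of their members lower. In the extraembryonic endoderm list, 18 of 30 tested members were lower and 1 higher (19 and 1 adjusted over the list alone), with Nid1, the growth-related RNA H19 (-4.35 ± 0.93, SE), the matrix protein gene Sparc (-4.17 ± 0.47) and the laminin gene Lamb1 (-4.02 ± 0.47) in front. Its median was -1.13 and its adjusted p = 1.01e-05, with an adjusted p = 0.415 with an estimated correlation, and its score was 6.20 to 6.48 in ES1 to ES12, 7.51 in ES13, 7.44 in ES14 and 7.48 to 8.50 in the arrays labelled C57BL/6. In the trophoblast list 7 of 17 were lower, led by Peg10 (-4.25), the placental gene Plac1 (-2.75), Gata3 (-2.10) and Tfap2c (adjusted p = 0.0141, adjusted p = 0.415 with an estimated correlation, and adjusted p = 0.192 without the dimmer 50% of genes). The trophoblast score was 6.05 to 6.42 in ES1 to ES12, 7.84 in ES13, 7.82 in ES14 and 7.01 to 7.69 in the arrays labelled C57BL/6. In the cardiac list 13 of 25 were lower and 1 higher (16 and 1 adjusted over the list alone), with the transcription factor genes Tbx20 (-3.74), Isl1 (-2.40), Gata6 (-1.46) and Gata4 (-1.32) named. The other lower members, contractile or not, are not named here. The list had an adjusted p = 0.00649, and an adjusted p = 0.428 with an estimated correlation. Its score was 5.65 to 6.15 in ES1 to ES12, 6.68 in ES13, 6.69 in ES14 and 6.30 to 7.07 in the arrays labelled C57BL/6. In the neural list 12 of 29 were lower, led by Sox11 (-2.86), the intermediate filament gene Nes (-2.74), Stmn2 (-2.62) and the adhesion gene Ncam1 (-2.52), with adjusted p = 0.00104 and an adjusted p = 0.415 with an estimated correlation, and scores of 5.67 to 6.09 in ES1 to ES12, 6.68 in ES13, 6.36 in ES14 and 6.36 to 7.08 in the arrays labelled C57BL/6. Of 32 Hox genes 13 were lower (14 lower and 1 higher adjusted over the list alone), with Hoxc5 (-1.20), Hoxd13 (-1.14), Hoxc9 (-0.91) and Hoxa11 (-0.81) named. The Hox list had an adjusted p = 0.0141, an adjusted p = 0.663 with an estimated correlation, and an adjusted p = 0.124 after quantile normalization. Its score was 5.50 to 6.44 in ES1 to ES12, 6.50 in ES13, 6.97 in ES14 and 6.05 to 6.92 in the arrays labelled C57BL/6. Hoxc9 did not pass with the median over all probe sets (-0.48, adjusted p = 0.115), and Hoxa11 differed by -1.35 there; with array weights Hoxc9 differed by -1.53.

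The primitive streak and gut lists did not pass. Of 26 primitive streak and mesoderm genes 5 were lower, among them the growth factor receptor Pdgfra (-2.67), Snai1 (-2.31), Rspo3 (-1.06) and the Notch ligand Dll1 (-0.44), and the list had an adjusted p = 0.21. Its score was 6.12 to 6.86 in ES1 to ES12, 8.65 in ES13, 7.87 in ES14 and 6.78 to 7.51 in the arrays labelled C57BL/6. Without ES1 to ES12 it passed as higher in ES13 and ES14 (median 0.83, adjusted p = 5.23e-15, and adjusted p = 0.0181 with an estimated correlation), with 1 of its 26 members past the threshold, and without ES13 and ES14 it passed as lower (median -0.35, adjusted p = 0.00808), with 12 members lower. Rspo3 differed by -1.59 with array weights, and Dll1 did not pass with arrays centred on their median (adjusted p = 0.0761). In the definitive endoderm list, 6 of 16 members were lower (7 adjusted over the list alone), including the keratins Krt19 (-4.45 ± 0.51, SE) and Krt18 (-2.72 ± 0.65). A further 3 were higher, including the chemokine receptor Cxcr4 (3.81 ± 0.37) and the homeobox gene Hhex (3.12 ± 0.30), both of which are also expressed in blood cells. The list had an adjusted p = 0.704.

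The fibroblast, imprinted and signalling target lists passed as lower in the arrays labelled 129S2/SvPas. Of 29 fibroblast and feeder genes 24 were lower and 2 higher, also when adjusted over the list alone, with fibronectin Fn1 (-4.69 ± 0.62, SE), the mesenchymal homeobox gene Prrx1 (-4.63 ± 0.45), the collagen gene Col1a2 (-4.03 ± 0.36) and periostin Postn (-4.02 ± 0.78) in front. The list median was -2.36 (adjusted p = 1.13e-10), and the adjusted p with an estimated correlation was 0.308. The list score was 5.89 to 6.50 in ES1 to ES12, 7.19 in ES13, 7.51 in ES14 and 7.23 to 9.27 in the arrays labelled C57BL/6. Of 30 imprinted genes 24 were lower (25 adjusted over the list alone), with Slc38a4, Rian, Peg3 and Mest (-4.65) named, a list median of -1.66, an adjusted p = 1.42e-08 and an adjusted p = 0.415 with an estimated correlation. The imprinted score was 6.17 to 6.56 in ES1 to ES12, 8.89 in ES13, 9.09 in ES14 and 7.85 to 9.72 in the arrays labelled C57BL/6. Of 26 Wnt, Nodal and BMP target genes 12 were lower, led by Msx2 (-2.58), Id3 (-2.52), the cyclin gene Ccnd1 (-2.33) and the feedback inhibitor Spry4 (-1.93), with adjusted p = 0.000917 and adjusted p = 0.415 with an estimated correlation. Msx2 differed by -1.20 with the median over all probe sets. The score of that list was 7.10 to 7.57 in ES1 to ES12, 9.12 in ES13, 8.74 in ES14 and 8.23 to 8.81 in the arrays labelled C57BL/6.

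**Figure D3:**
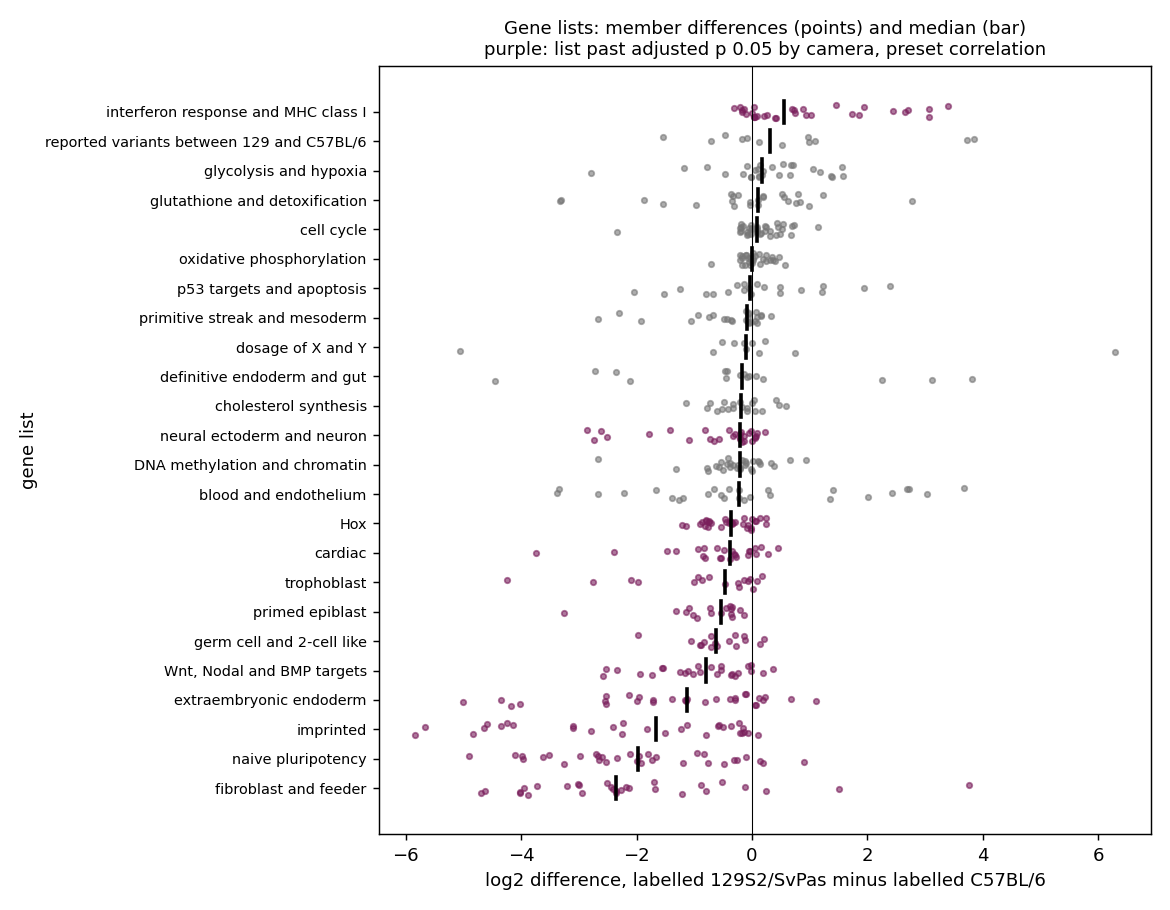
Log2 difference, labelled 129S2/SvPas minus labelled C57BL/6, of each tested member (points) and the median (bar) of the 24 gene lists, with purple for lists past an adjusted p of 0.05 by camera with the preset correlation. The fibroblast list has the lowest median, -2.36, and the interferon and MHC class I list is the 1 purple list with a median above 0, 0.56.

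The interferon response and MHC class I list was the 1 list that passed as higher in the arrays labelled 129S2/SvPas. Of its 32 tested genes, 16 were higher and 0 lower, also when adjusted over the list alone, led by the immunoproteasome genes Psmb8 (3.39 ± 0.29, SE) and Psmb9 (3.07 ± 0.33), the class I gene H2-D1 (3.07 ± 0.44) and the peptide transporter Tap2 (2.70 ± 0.35). The median was 0.56 (adjusted p = 4.13e-05), and the adjusted p with an estimated correlation was 0.415. The difference of Psmb9 was 0.80 with the median and 1.56 with the mean over all probe sets. The list score was 7.35 to 7.96 in ES1 to ES12, 6.75 in ES13, 6.20 in ES14 and 6.17 to 6.94 in the arrays labelled C57BL/6. H2-D1 lay between 12.06 and 12.51 in ES1 to ES12, at 8.34 in ES13 and 7.70 in ES14, and between 8.05 and 9.05 in the arrays labelled C57BL/6.

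Blood genes moved in both directions. Of 27 blood and endothelium genes, 8 were higher and 10 lower (11 lower adjusted over the list alone). The higher genes included the transcription factors Fli1 (3.68 ± 0.59, SE) and Spi1 (3.04 ± 0.44), and the lower ones the embryonic globins Hbb-y (-3.38 ± 0.98) and Hbb-bh1 (-3.35 ± 1.21). Hbb-bh1 did not pass by the rank sum test (adjusted p = 0.0767) and differed by -5.44 with array weights. It spanned 2.90 to 4.04 in ES1 to ES12, 7.10 in ES13, 10.67 in ES14, and 2.82 to 12.67 in the arrays labelled C57BL/6. The list did not pass (adjusted p = 0.972), and its test direction was up while its median (-0.22) and mean (-0.02) were below 0.

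The lists of cell processes did not pass with camera. Of 36 cell cycle genes 11 were higher, including Ccnd2 (1.15 ± 0.22, SE), the proliferation marker Mki67 (0.72 ± 0.12) and the replication inhibitor Gmnn (0.70 ± 0.16), and Ccnd1 was lower. Of 27 glycolysis and hypoxia genes 9 were higher and 2 lower, with Egln3 (1.58), Car9 (1.56) and Ndrg1 (1.38) higher and the collagen hydroxylase P4ha2 (-2.79) lower. The cell cycle and glycolysis lists each had an adjusted p = 0.0599, and the glycolysis list one of 0.0232 with the first principal component as a covariate. The glycolysis list passed as higher without ES13 and ES14 (adjusted p = 0.00916, 14 members higher) and as lower without ES1 to ES12 (median -0.45, adjusted p = 0.000119, and adjusted p = 0.215 with an estimated correlation), where the cell cycle list passed as higher (adjusted p = 0.00417, and adjusted p = 0.715 with an estimated correlation). Of 20 p53 and apoptosis genes 6 were higher, including Pmaip1 (2.39) and Cdkn1a (1.94), and 6 lower, including Eda2r (-2.05) and Phlda3 (-1.53). Of 25 glutathione and detoxification genes 7 were higher and 5 lower, with Gstm1 at 2.78, Gsta4 at -3.32, Cyp1b1 at -3.32 and Akr1b8 at -1.87. Oxidative phosphorylation had 4 of 30 higher and 3 lower, among them Sdhd (0.57), Uqcrfs1 (0.48), Ndufb8 (0.37) and Nnt (-0.70). Uqcrfs1 did not pass with the median or mean over all probe sets (adjusted p = 0.23 and adjusted p = 0.068), nor Ndufb8 with the mean (adjusted p = 0.0908). Cholesterol synthesis had 3 of 20 higher and 5 lower, with Hmgcs1 (-1.15), Lss (-0.77), Fdft1 (-0.73) and Msmo1 (-0.60) lower. DNA methylation and chromatin had 3 of 31 higher and 9 lower, with Tet1 (-2.66) and Rnf2 (-0.77) lower and Chd7 (0.93) higher. The adjusted p of these 5 lists lay between 0.114 and 0.972, and the list of DNA methylation and chromatin passed as lower after quantile normalization (adjusted p = 0.0127) and by fry (adjusted p = 0.0464). In the p53 list (test up, median -0.03, mean 0.08) and the glutathione list (test up, median 0.10, mean -0.12), median, mean and test differed in sign.

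The list of X and Y dosage did not pass (camera adjusted p = 0.972), with 4 of its 11 tested genes past the threshold. Of these, Xist (6.30 ± 0.76, SE) and the X-linked demethylase Kdm6a (0.74 ± 0.15) were higher, and Eif2s3y (-5.07 ± 0.66) and Uba1y (-0.52 ± 0.16) lower. The test direction was down, with a median of -0.11 and a mean of 0.05. Because X-linked and Y-linked genes of this list moved in opposite directions, a test for a shared direction cannot decide whether they differ. Xist lay at 12.00 or higher in ES1 to ES12 and at 5.98 or lower in all other arrays. Eif2s3y lay at 4.03 or lower in ES1 to ES12 and at 7.87 or higher in all other arrays. Uba1y did not split in this way. It lay between 5.40 and 6.33 in ES1 to ES12, at 6.23 in ES13 and 6.06 in ES14. In the arrays labelled C57BL/6 it lay between 6.00 and 7.85, highest in ES23. Genes reported to carry variants between the strain backgrounds did not pass with camera (adjusted p = 0.347) and passed as higher by fry (adjusted p = 0.00544). Of 12 tested, the inflammatory caspase Casp4 (3.85 ± 0.65, SE), Naip5 (3.74 ± 0.52), Trim12a (1.10 ± 0.22), Entpd4 (0.99 ± 0.26) and Nlrp1b (0.98 ± 0.21) were higher, and Glo1 (-1.54 ± 0.17), Nnt (-0.70 ± 0.18) and Wdfy1 (-0.46 ± 0.14) lower. Wdfy1 did not pass with the median (-0.33, adjusted p = 0.103) or the mean over all probe sets (-0.13, adjusted p = 0.434), and 0.5 of its probe sets shifted with the gene. The difference of Trim12a was 3.27 and 3.10 in these 2 settings. Disc1 (-0.09), Cdh23 (0.13), Mx1 (-0.17) and Ide (0.51) did not pass, though Cdh23 (0.26, adjusted p = 0.00516) and Ide (0.65, adjusted p = 0.021) did with arrays centred on their median. Uba1y did not pass after quantile normalization (adjusted p = 0.0566), and its difference of medians was -0.27. Casp4 was 3.65 in ES13 and 3.64 in ES14, against 7.99 to 10.05 in ES1 to ES12 and 3.16 to 6.36 in the arrays labelled C57BL/6.

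In all, 12 of 24 lists passed with the preset correlation, 11 lower and 1 higher. With a correlation estimated from the arrays, 0 passed by camera (2 had an unadjusted p below 0.05), and fry, which tests whether a list's genes move one way without comparing them with other genes, called 14. Without ES1 to ES12, of the 11 lists called lower 1 passed as lower, fibroblast and feeder (adjusted p = 0.000242), and 4 passed in the opposite direction, higher in ES13 and ES14: primed epiblast (adjusted p = 0.00462), trophoblast (adjusted p = 0.0132), Hox (adjusted p = 0.0036) and the Wnt, Nodal and BMP targets (adjusted p = 0.00124). In these 5 lists 0 members passed the threshold there, with 2 arrays in 1 of the groups. With an estimated correlation the Wnt, Nodal and BMP targets passed (adjusted p = 0.0329), and primed epiblast (adjusted p = 0.525), trophoblast (adjusted p = 0.098), Hox (adjusted p = 0.325) and fibroblast (adjusted p = 0.414) did not. The other 6 and the interferon list did not pass there. Of the 12 lists not called with all arrays, 6 passed as higher without ES1 to ES12 and 3 as lower, and of these 9 the primitive streak list passed with an estimated correlation.

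At the level of single probe sets, 181661 of 631748 passed the threshold, 89667 higher and 91994 lower in the arrays labelled 129S2/SvPas. Of the probe sets with 1 gene symbol, 112835 of 306069 passed (36.9%), and of the others 68826 of 325679 (21.1%). Without ES1 to ES12, 55 passed.

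Within genes, single probe sets departed from the rest of their gene. For the ribosomal protein gene Rplp0, probe set 4369920 averaged 12.19 in the arrays labelled 129S2/SvPas and 6.15 in those labelled C57BL/6, while the gene value was 12.83 and 12.59, a difference of 0.24 (adjusted p = 0.00425). Relative to the gene it differed by 5.80 ± 0.71 (SE; limma adjusted p = 2.81e-06), and lay at 0.22 to 0.53 in ES1 to ES12, -6.36 in ES13 and -6.79 in ES14. For the snoRNA host gene Gas5, whose gene value was higher by 0.78 (adjusted p = 0.00508), probe set 5552284 differed by 5.60 ± 0.74 and lay at -6.36 in ES13 and -8.09 in ES14. Samsn1 had the largest relative difference (probe set 5614356, 6.76 ± 0.98) beside a gene value that differed by -1.46 (adjusted p = 0.000309). However, only 0.472 of the 36 probe sets of Samsn1 shifted with its gene value. A probe set of the Wnt receptor gene Fzd2 went the other way (4589376, -5.46 ± 0.59), with a gene difference of 0.25 (adjusted p = 0.181). For Fzd2, 0.167 of the probe sets shifted with the gene value. The relative differences of Ela2 (5599213, -5.65) and Cpa3 (4448551, -5.55) came with gene differences of 5.84 and 6.77, so the probe set stayed bright while the gene was dim. In total 6698 of 156023 probe sets passed, 3342 higher and 3356 lower, in 2296 genes. With only the brightest 25% of genes and probe sets 915 passed, and without ES1 to ES12 6 passed.

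The test of spread within each label called few genes with all arrays. In simulation it recovered 30.5% of genes with a 4-fold larger SD, so few calls do not mean few differences. Eosinophil peroxidase Epx was more variable in the arrays labelled 129S2/SvPas (SD 2.32, n = 14) than in those labelled C57BL/6 (SD 0.16, n = 12, adjusted p = 0.00408). It lay between 6.01 and 12.16 in ES1 to ES12. The interleukin receptor Il2ra, Arg1, the granzyme gene Gzmb, Fgfr1 and Fbp1 were also more variable in the label 129S2/SvPas. Fgfr1 lay between 6.19 and 8.64 in ES1 to ES12, but was 10.61 in ES13 and 10.57 in ES14. More variable in the arrays labelled C57BL/6 were the mesothelial gene Msln (SD 2.02 against 0.15, adjusted p = 0.00272), the endothelial gene Emcn (SD 2.02 against 0.26, adjusted p = 0.00203), the proteoglycan gene Dcn, the retinoic acid receptor Rarb, Ttr and Gata6os. Msln lay between 5.31 and 5.65 in ES15 to ES20 and between 7.55 and 10.03 in ES21 to ES26, while Emcn lay between 7.41 and 9.05 in ES15 to ES20 and between 4.04 and 4.75 in ES21 to ES26. Of 18341 genes 239 passed by limma, 20 wider in the label 129S2/SvPas and 219 in C57BL/6 (351 and 948 with deviations from the mean). The count was 0 or 1 whenever any of ES15 to ES26 was left out (2158 to 2484 genes with an unadjusted p below 0.05, and Msln the gene in the 4 settings with 1), 75 to 143 when any of ES1 to ES12 was left out, and 1299 both with deviations from the mean and without ES13 and ES14. Without ES13 and ES14, 103 of the 1299 genes were wider in the label 129S2/SvPas. With deviations from the mean 2868 passed there, 317 wider in 129S2/SvPas and 2551 in C57BL/6.

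List scores formed separate clusters within both labels, so no correlation between them is given. The largest gap between neighbouring naive pluripotency scores took up 60.7% of the range within the label 129S2/SvPas and 57.6% within C57BL/6. In the latter, ES21 to ES24 scored 10.15 to 10.77, and the other 8 arrays 7.20 to 8.09.

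**Figure D4:**
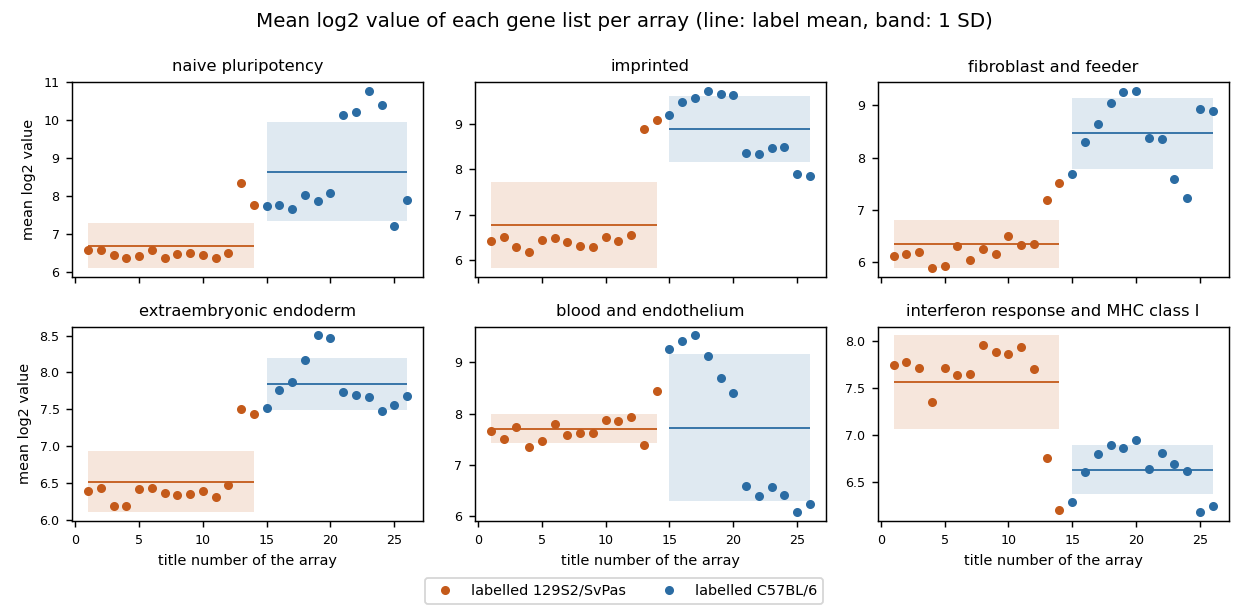
Mean log2 value of 6 gene lists on the vertical axes against the title number of the array, with orange points for the label 129S2/SvPas, blue points for C57BL/6, a line at each label's mean and a band of 1 SD. The naive pluripotency score is highest in ES21 to ES24 at 10.15 to 10.77, and the blood and endothelium score is highest in ES17 at 9.53.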

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

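The settings without ES13 and ES14, and without ES1 to ES12, were chosen after the data were seen; the others were planned. No named gene, named probe set or list turned direction under the planned settings in which it passed or had passed. Of genes called in both, 6689 of 6696 had the same direction with the median over all probe sets and 7204 of 7210 with their mean, and every one in the other planned settings. The gene-level count lay between 5818 and 9842 under all planned settings but those named next: 4841 with the dimmer 50% of genes left out, where fewer genes were tested, and 5049 with a 1.5-fold minimum, a stricter rule. Of the 7931 genes, 7850 were called in the same direction without ES13 and ES14, where 9250 passed. Without ES1 to ES12, 1 gene passed, 55 probe sets and 6 probe sets within genes, with 14 arrays left. Of the named genes past the threshold, 110 came from the largest differences or the picks per gene list. Without ES13 and ES14, 110 kept their direction and call. Without ES1 to ES12, 50 kept their direction and 0 their call. Genes named only for a probe set left out, 125 named genes passed the threshold. Of these, 15 lost the call in 1 or more of the planned settings that are no stricter rule. Moves of over 1.5 times were seen for 25, and 0 turned direction. The losses were those of Sycp3, Hoxc9, Uqcrfs1, Ndufb8, Wdfy1, Uba1y, Dnmt3b, Dll1, Ddx4, Hbb-bh1, Hormad1, Msln, Ttr, Gata6os and Emcn. At an adjusted p of 0.01, 120850 probe sets passed, a stricter rule. Within genes, 14823 passed with a 1.5-fold minimum, a looser rule, and 915 among the brightest 25%. For gene lists, 0 passed with an estimated correlation. Without ES1 to ES12 14 lists passed (2 with an estimated correlation), 71.4% of them higher, and of the 11 called lower 4 turned and passed as higher, primed epiblast, trophoblast, Hox and the Wnt, Nodal and BMP targets (adjusted p of 0.00462, 0.0132, 0.0036 and 0.00124). Primed epiblast and trophoblast did not pass without the dimmer 50% of genes (both 0.192). The spread count was 1299 with deviations from the mean, 41 without the dimmer 50% of genes, 373 after quantile normalization and 1299 without ES13 and ES14; the cause was not tested. Leaving out 1 array at a time gave 7536 to 8631 genes, 12 to 14 lists, and 0 to 319 genes for the spread, where 24 of 26 omissions moved the count by over 1.5 times, the exceptions being ES13 and ES14. An odd number of arrays puts the median on an array and an even number between arrays, and with deviations from the mean the spread count lay between 1014 and 1477 over the same omissions. With the median as list score, the largest gap in the label C57BL/6 took up 47.1% of the range, and the cause was not tested. No paired analysis was possible because the labels give no replicate numbers shared between the strains. Signal near background limits the dimmest genes, for which differences are understated.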

Other observations

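Embryonic globin transcripts were high in ES14 to ES20, given here as values per array since the labels name no such group. The embryonic globin Hbb-bh1 was 7.10 in ES13, 10.67 in ES14 and highest in ES16 at 12.67, and it was 9.74 in ES20, while ES1 to ES12 lay between 2.90 and 4.04 and ES21 to ES26 between 2.82 and 4.25. A second embryonic globin, Hbb-y, was 11.44 in ES14 and 12.90 to 13.84 in ES15 to ES20, but 6.77 in ES13, within the 6.19 to 7.42 of ES21 to ES26. The definitive erythroid list score was 6.13 in ES13, 9.72 in ES16 and 8.21 in ES20, and 5.79 to 6.55 in ES1 to ES12 and 5.41 to 5.82 in ES21 to ES26. The adult globin Hbb-b1, a gene of that list, lay between 7.96 and 12.55 in ES1 to ES12 and was 10.86 in ES20. The erythroid list score and both embryonic globins were highest in ES16, so the score cannot tell definitive from embryonic red cells. The megakaryocyte list score was 5.93 in ES13, highest in ES17 at 9.99 and 9.19 in ES20, against 6.61 to 8.04 in ES1 to ES12 and 5.78 to 6.18 in ES21 to ES26. Platelet factor Pf4 was 5.39 in ES13 and 11.80 in ES17, and lay between 7.18 and 9.54 in ES1 to ES12. Mixl1, a primitive streak gene, was 10.95 in ES13, 8.93 in ES14 and 5.55 to 6.99 in ES15 to ES26. The proteoglycan gene Dcn was 4.22 in ES13 and 10.51 in ES20, and the retinoic acid receptor Rarb 5.08 and 10.29.

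The naive pluripotency gene Dppa5a lay between 11.84 and 12.66 in ES21 to ES24. Of the named primed epiblast genes, Dnmt3b (11.23) and Fgf5 (8.10) were highest in ES13, and Cldn6 (9.87) and Otx2 (8.24) in ES23. The primed epiblast score was 8.36 in ES13 and 8.40 in ES23, so it did not set these arrays apart. ES25 and ES26 had Dppa5a at 7.34 and 8.87 and naive pluripotency scores of 7.20 and 7.88, with fibroblast scores of 8.94 and 8.89. B cell and T cell list scores differed little over the 26 arrays, at 5.08 to 5.68 and 5.35 to 5.93. Single members did not all stay level. Tcf7 of the T cell list lay between 6.40 and 7.42 in ES1 to ES12 and between 8.16 and 10.66 elsewhere. In the B cell list, Ebf1 was 4.92 to 5.70 in ES1 to ES12 and 5.94 to 7.86 elsewhere, while Cd79b reached 8.70 in ES1 and at most 6.75 in ES13 to ES26. The blood stem and progenitor score was 9.24 to 9.50 in ES1 to ES12 and 6.21 to 8.13 in ES13 to ES26. Over the same arrays, the myeloid score was 11.13 to 12.09 and 5.24 to 7.15. Members of the stem and progenitor list did not move alike, so its score does not stand for all of them. Ptprc lay at 10.62 or higher in ES1 to ES12 and at 7.48 or lower elsewhere. Meis1 went the other way, at 4.72 to 6.95 in ES1 to ES12 and 10.19 to 10.34 in ES17 to ES20.

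All tests in this part were chosen, and their outcomes written down, only after the results they measure had been seen in whole or in part. ES1 to ES12 stood apart from all other arrays, and 5768 of the 7931 genes called by strain label had ES13 and ES14 both nearer to the mean of the other label than to ES1 to ES12. A difference between the strains as labelled is argued against, since each of ES13 and ES14 correlated better with the other label, by at least 0.111. Blood cells of the myeloid line are a candidate source of ES1 to ES12: their lowest myeloid score lay 3.98 above the highest elsewhere, with Mpo at 11.97 or higher and S100a8 at 11.86 or higher, but the lowest member, Csf1r, at 8.68 in ES1 and up to 9.02 in ES20, and of the list's 14 genes 0 were in another list, 4 passed 8 in any of ES13 to ES26, and 2, Ngp and Mmp8, were among the 12 largest differences, without which the gap was 3.58; the list was written after ES1 to ES12 were seen to stand apart. Strain labels given in reverse order may add to this, on an array designed on C57BL/6 sequence. For genes above 8 in all arrays, each probe set was taken relative to its gene and compared with its array ranked 3 from the top. Only probe sets near or above their gene in that array were used. Of these, 31 lay over 3 log2 units below that array in all of ES13 to ES26 and none of ES1 to ES12. The other way round there were 13, a ratio of 2.38. A probe set counted so need not lie below its gene. Several of the 13 came from the same gene, Mtm1, so these are not counts of separate genes. Exon use that differs between cell types stays open as a cause of those probe set differences. So does a difference in strain or cell source that the labels do not give. The values of Xist and Eif2s3y go with a difference in cell source between ES1 to ES12 and the other arrays. Xist lay at 12.00 or higher in ES1 to ES12 and at 5.98 or lower elsewhere. Eif2s3y lay at 4.03 or lower in ES1 to ES12 and at 7.87 or higher elsewhere.

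Arrays with neighbouring title numbers resembled each other. Among the 12 arrays labelled C57BL/6, neighbours had a mean gene correlation of 0.975 against 0.942 over all pairs, which a shuffled order reached with p = 2e-05 (one-sided permutation test, 100000 orders). Among ES1 to ES12 the values were 0.979 and 0.975, with p = 0.0416 in the same test. The titles may therefore follow an order, but the test cannot tell a gradual order from blocks of like arrays. The naive pluripotency score was 7.67 to 8.09 in ES15 to ES20, 10.15 to 10.77 in ES21 to ES24, and 7.20 and 7.88 in ES25 and ES26. Time in culture and an order of processing were not tested separately.

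Whether chance splits of the samples could give such counts was checked by drawing other splits into groups of 14 and 12. For the gene-level count of 7931, 1 of 100 splits, the real one, gave as many, and the highest other gave 1. For the spread count of 239 it was 1 of 100, with 39 as the highest other. For the 181661 probe sets it was 1 of 30 splits and for the 6698 probe sets within genes 1 of 50, with 0 as the highest other in both. That excludes chance for the counts of genes, probe sets and probe sets within genes if arrays are interchangeable. However, neighbouring arrays resemble each other, and splits drawn at random break up their runs. For the spread the splits cannot decide, because random groups mix ES1 to ES12 with the other arrays and so widen the spread within both groups. The spread count also fell to 0 or 1 when any of ES15 to ES26 was left out. With the run of 14 moved round the title order instead, 5 of 26 placements, the real one included, gave as many genes, probe sets and probe sets within genes, and 3 gave as many genes for the spread, the highest others being 9615, 239910, 9153 and 956, all with the run from ES13 to ES26. These counts therefore point to a structure of the samples in title order, and chance is not excluded for where in that order the label falls. For the 12 gene lists, 27 of 100 splits gave as many and the highest other gave 17, and 18 of the 26 placements gave as many, so chance is not excluded for the number of lists.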
